A study of Mus musculus with 4 samples.

How the data were processed

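Total RNA was measured by sequencing in islets of Langerhans, the hormone-secreting cell clusters of the pancreas, from male mice aged 3 to 4 months. Per the labels' protocols, each library was made from about 300 islets pooled from 2 to 3 mice, ribosomal RNA was removed with a hybridization kit, and libraries were built with a directional, randomly primed kit. Of the 4 libraries, 2 came from non-transgenic control mice (replicates 1 and 2) and 2 from mice with Tafazzin knocked down (replicates 3 and 4). Both groups were on the same diet. Since the controls were non-transgenic, an effect of the transgene itself cannot be told apart from an effect of Tafazzin depletion. The groups share no replicate number, so no pairing was used. The libraries are separate pools of mice.

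The authors deposited 1 table with a value per gene and library. STAR 2.5.1b, HOMER 4.9, edgeR and the genome build mm10 are named, without roles, per the submitters' processing notes. The table's name announces FPKM, but the deposited values are a signal in reads per 10000000 reads of the library total, with no scaling by gene length. In each library 100% of the values were whole multiples of 1 step, within 0.01 reads, so that whole reads could be recovered. The recovered library totals were 68823160 and 81073502 reads for control replicates 1 and 2, and 76680282 and 78630832 reads for knockdown replicates 3 and 4. A single read is therefore worth 0.123 to 0.145 units.

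The length column equals the genomic span of the gene, introns included, for 99.2% of the 24940 genes, and genes on opposite strands at 1 place hold nearly equal values. The values were therefore read as counts over whole gene bodies without regard to strand, although no source used here states the counted region. Of the genes, 6099 overlap another gene of the table, and their reads cannot be told apart from those of the partner. Coordinates are those of the deposited table, on mm10. Genes of the mitochondrial genome were not analysed here.

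The row of the 45S ribosomal RNA precursor, Rn45s, took 41.6% to 42.6% of the reads, with a Wilson 95% interval at most 0.0233 percentage points wide, which covers counting error only. Together with 12 other rows above 25000 units (Ins1 and Ins2 not among them), it held most of the reads counted in the table. All other genes held 6.68% and 5.33% of the library totals in the controls and 6.32% and 6.31% in the knockdown libraries. That is 4595617, 4320910, 4849596 and 4962798 reads, called reads outside the 13 rows, which limit the precision of counting. Summed over all rows, the table held 55470964 and 65175895 reads in the controls and 62167624 and 63674275 in the knockdown libraries. In these sums and those above, a read in overlapping rows can be counted more than once. Even so the sums over all rows are below the library totals, so that some reads lay in no gene of the table.

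The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, a two-sided test and Benjamini-Hochberg adjustment at 0.05. The fit estimated infinite prior degrees of freedom, so that the spread of each gene between pools was replaced by the trend over all genes at its level. A gene whose own libraries vary more than that trend can therefore be called although its groups overlap, as 4 of the higher and 3 of the lower calls were. After median-ratio scaling the prior degrees of freedom were 21.3. A fold change on this scale understates the change of genes at low values. Genes entered with a mean of at least 1 unit and a length of at least 200 nt, which left 13531 genes. The test, the filters, the pseudocount, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The plan had assumed FPKM, with the quasi-likelihood test of edgeR to replace limma if the file held counts. The unit turned out to be reads per 10000000 reads, from which counts could be recovered. The limma test on a log scale was nevertheless kept as the main test. Count tests on the recovered reads were added beside it afterwards.

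The median log2 fold change of all tested genes was 0.17 rather than 0. Log2 fold changes are therefore given relative to this median, with their standard error (SE), whereas the limma p-values test the unshifted change against 0.

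Of 33 gene lists, 29 had at least 5 tested members and were tested with camera, from limma, which compares a list with all other genes, at a preset correlation of 0.01. The test was repeated with a correlation estimated per list, and fry was run as a test of each list on its own. Camera and fry p-values were adjusted over the 29 lists. Counts of called members are given after adjustment over all genes and adjusted over the list alone.

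Named genes are Taz; the 12 higher and the 12 lower called genes with the largest absolute log2 fold change among those whose knockdown libraries both lay outside the range of the controls; of each list with at least 5 tested members, the most abundant member and the 2 members with the largest absolute moderated t; and a fixed set of islet genes, among them Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Kcnj11 and Abcc8. A few genes that the rule selects are not reported here. Under the rule for called genes, predicted gene models and microRNA or small nucleolar RNA rows were counted but not named. A few other genes are named where a text says that they were chosen after their values were seen.

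The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 units, no minimum length, median-ratio scaling, quantile normalization, a fit without trend, a robust fit, a 10% threshold, and leaving out each library. In the latter fits the lone library of a group is assumed to vary like those of the other group. The quasi-likelihood test of edgeR 4.0.16, planned as the main test for counts, was run on the recovered reads as an alternative. Alternatives added after seeing the data were DESeq2 1.42.0 on the recovered reads and a fit of genes that overlap no other row. Also added were scaling to the reads outside the 13 rows above 25000 units other than Ins1 and Ins2, and median-ratio scaling combined with leaving out each library.

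Within groups the recovered reads of the 2 controls had a chi-square per degree of freedom of 6.79 and those of the 2 knockdown libraries 5.96, far above sampling noise, so no library was treated as a copy of another. Between groups the values were 10.3 and 5.97 for control replicate 1 against knockdown replicates 3 and 4, and 6.93 and 6.70 for control replicate 2. The limma procedure was tested on simulated data with the real means and totals, a dispersion of 0.0168 and 200 changed genes among 13533 tested. It called 14.9% of the genes changed 1.5-fold, 73.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 2 false calls. In simulated data with 1 list shifted 1.5-fold, camera called that list and 0 others. The stated settings of the simulation hold no correlation between genes. The correlations estimated in the real data were 0.283 for stellate markers and 0.844 for beta cell identity genes. The simulation therefore does not measure how often list calls are false here. Its stated settings also hold a single dispersion for all genes, so that no gene varies more than the trend. The 2 false calls are thus no measure of how often calls of single genes are false here. Figures were drawn with matplotlib 3.10.9.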

Results

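Gene expression was measured in pancreatic islets of 2 control libraries and 2 Tafazzin-knockdown libraries, each a pool of islets from 2 to 3 male mice. The design asks how the islet transcriptome differs when Tafazzin, the mitochondrial transacylase that remodels cardiolipin, is depleted. Values are reads per 10000000 reads of the library total, called units, and were apparently counted over whole gene bodies without regard to strand. The libraries held 68823160 and 81073502 reads in control replicates 1 and 2, and 76680282 and 78630832 reads in knockdown replicates 3 and 4. The median log2 fold change of all tested genes was 0.17 (-0.01 after median-ratio scaling). Log2 fold changes are given relative to this median, whereas limma p-values test the unshifted change against 0.

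Taz, the gene of Tafazzin (NM_181516; mm10 chromosome X, 74282718 to 74290151, plus strand), was read at 23.1 and 15.4 units in control replicates 1 and 2. It stood at 13.8 and 12.7 units in knockdown replicates 3 and 4. These values rest on 159, 125, 106 and 100 reads. The mean was 19.3 ± 5.43 units in the controls and 13.3 ± 0.782 in the knockdown (SD, n = 2 each), a ratio of 0.689. Both knockdown libraries lay below both controls, in the direction of the labels, but the difference did not pass the test (log2 fold change -0.65 ± 0.25 SE, limma adjusted p = 0.529). The edgeR test on the recovered reads gave an adjusted p of 0.126. Reads from introns are included in these values, and Taz overlaps no other gene of the table. Wwtr1, a different gene whose protein is also called TAZ, was named after its values were seen. It rose from 10.5 and 7.65 to 32.3 and 17.3 units (limma adjusted p = 4.95e-05).

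In the knockdown islets 337 genes rose and 6 fell among 13531 tested with limma, so that 98.3% of the calls were higher. In 4 of the higher and 3 of the lower calls the groups overlapped, since the test took the spread from a trend over all genes. The increases took in 14 of 21 markers of stellate cells and fibroblasts, 6 of 17 endothelial markers and 7 of 15 duct markers. The largest increases included Fbln2, an elastic-fibre protein, from 4.21 and 5.43 to 52.9 and 26.5 units (log2 fold change 2.57 ± 0.26 SE, limma adjusted p = 3.38e-22). For Fbln2 the limma adjusted p was 1.06e-05 after median-ratio scaling and the edgeR adjusted p was 4.32e-06. Selp, the adhesion receptor P-selectin of platelets and endothelium, rose from 4.36 and 4.19 to 53.2 and 21.1 units. It overlaps Gm16548, which holds up to 0.254 of its level. Fn1, which encodes fibronectin, rose from 2.91 and 2.22 to 29.5 and 16.3 units (2.53 ± 0.28 SE, limma adjusted p = 9.04e-19). For Fn1 these 2 other tests gave adjusted p of 1.64e-05 (limma after scaling) and 9.47e-06 (edgeR). Cdh6, a cadherin, rose from 1.16 and 0.493 to 17.2 and 8.39 units, and Myof, a membrane-repair protein, from 5.23 and 4.69 to 34.4 and 21.1 units. The matrix metalloprotease gene Mmp2 went from 1.16 and 2.96 to 18.8 and 9.41 units, and the cytokine gene Il11 from 6.10 and 18.0 to 59.5 and 43.9 units. The remaining genes of the 12 named increases were the water channel Aqp1, the carbonic anhydrase Car2, the potassium channel Kcnn4, the endocytic adaptor Epn3 and the ligand Wnt7b. Their log2 fold changes lay between 2.00 for Epn3 and 2.15 for Wnt7b. In control replicates 1 and 2 Epn3 stood at 0 and 1.23 units and Wnt7b at 0 and 0.740. At such low values the size of the fold change depends on the pseudocount. The edgeR log2 fold changes were 2.96 for Epn3 and 3.62 for Wnt7b. Without knockdown replicate 3 these 5 genes were no longer called, with limma adjusted p from 0.123 for Aqp1 to 0.422 for Car2.

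Only Scarna6 and Derl3 met the naming rule among the genes that fell. Scarna6, a small Cajal body RNA inside Atg16l1, fell from 10.6 and 11.6 to 5.35 and 1.65 units. The row of Atg16l1 holds 5.59 times its level. With no filter on low values Scarna6 and Derl3 were not called (limma adjusted p = 0.132 and 0.167). Derl3, a component of endoplasmic reticulum-associated degradation, fell from 4.65 and 4.69 to 0.782 and 2.04 units (log2 fold change -1.45 ± 0.38 SE, limma adjusted p = 0.0305). Scarna6 was not called without knockdown replicate 4 (limma adjusted p = 0.214). Derl3 was not called after median-ratio scaling (limma adjusted p = 0.0604), by edgeR (adjusted p = 0.0824) or without control replicate 1, control replicate 2 or knockdown replicate 3 (limma adjusted p = 0.0804, 0.203 and 1.0).

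Knockdown replicate 3 stood farthest from the controls. On a first principal component with 52.4% of the variance, the controls lay at -27.1 and -11.2, knockdown replicate 3 at 31.2 and knockdown replicate 4 at 7.04. The chi-square per degree of freedom between control replicate 1 and knockdown replicate 4 was 5.97, below the 6.79 between the 2 controls. The number of calls depended on scaling and on single libraries. After median-ratio scaling 151 genes were higher and 22 lower (87.3% higher), of which 150 and 2 were also called on the deposited values. The edgeR test called 171 higher and 20 lower, and 146 higher and 2 lower genes were called in all 3 ways. DESeq2 called 59 higher and 9 lower, of which 58 and 0 were also called by limma on the deposited values. Without knockdown replicate 3 the limma test called 26 higher and 4 lower genes, and without control replicate 1 it called 1264 and 37. The lower calls numbered 59 without control replicate 2 and 3 without knockdown replicate 4. With median-ratio scaling and either control left out 0 genes were called by limma, at 731 and 1256 genes with an unadjusted p under 0.05 without control replicate 1 and 2.

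**Figure D1:**
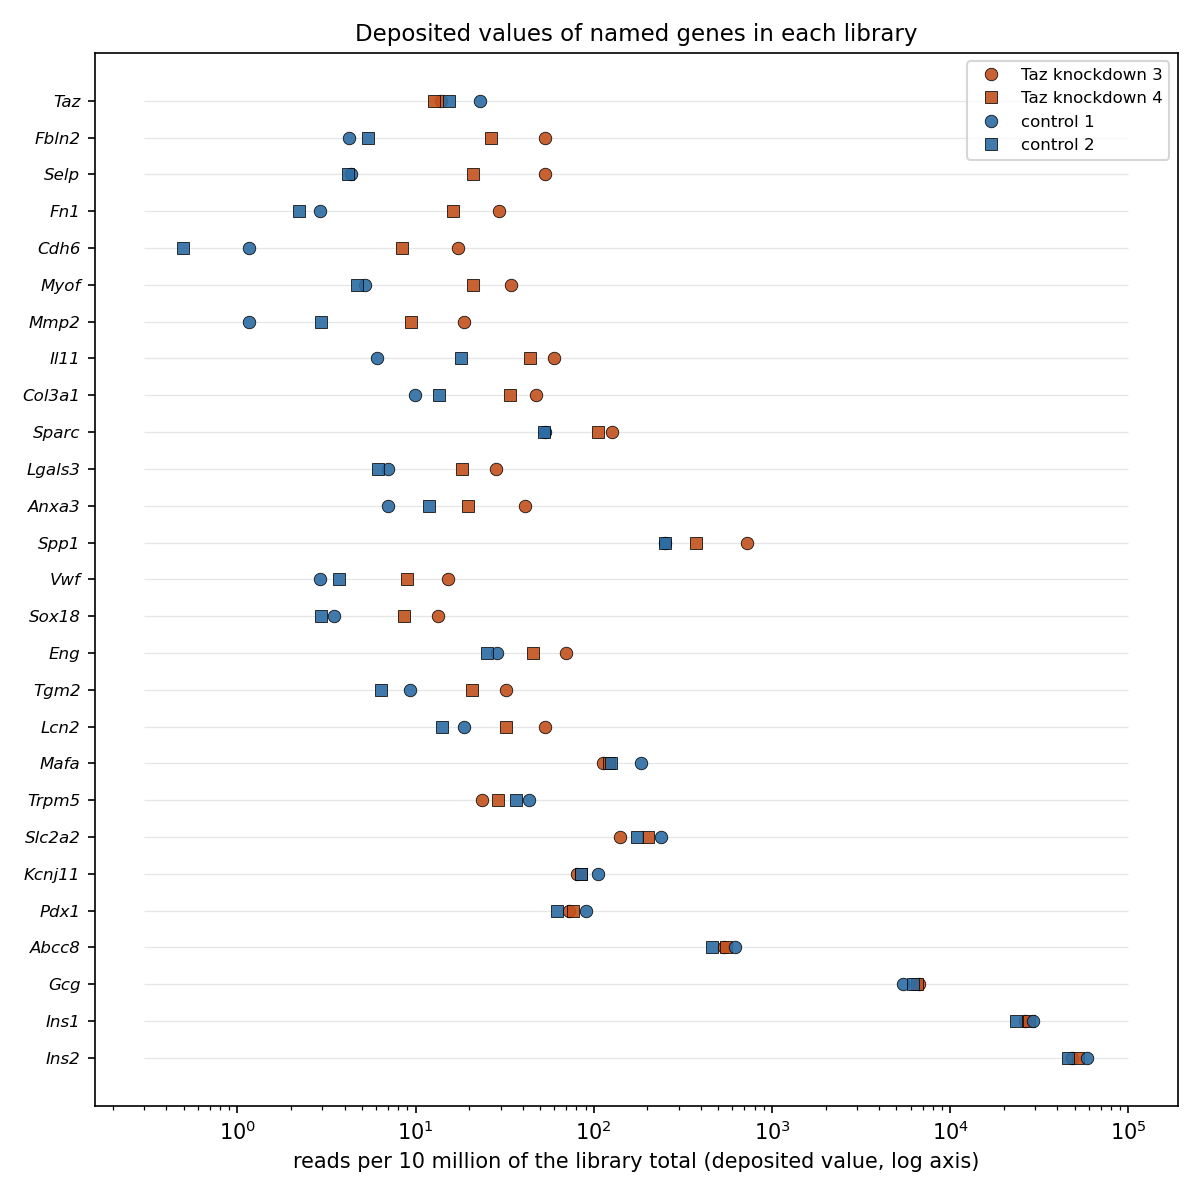
Deposited values of 27 named genes in each of the 4 libraries, in reads per 10000000 reads of the library total on a log axis. Points are single libraries, blue for control (circle, replicate 1; square, replicate 2) and orange for knockdown (circle, replicate 3; square, replicate 4). Taz lies lower in both knockdown libraries than in both controls, Fbln2 (4.21 and 5.43 against 52.9 and 26.5) and the other matrix, vessel and duct genes lie higher, and the insulin genes Ins1 and Ins2 overlap.

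Markers of stellate cells, fibroblasts and pericytes, the connective-tissue cells of the pancreas, showed the largest shift of any tested list. Of 21 tested members 14 rose and none fell by limma over all genes, 19 rose adjusted over the list alone, and all 21 lay above the median of all genes. Their median log2 fold change was 1.13 (camera adjusted p = 5.90e-44; adjusted p = 0.738 with an estimated correlation). Col3a1, a fibrillar collagen, rose from 9.88 and 13.6 to 47.5 and 33.8 units (1.54 ± 0.25 SE, limma adjusted p = 8.17e-09). For Col3a1 the limma adjusted p was 2.23e-04 after median-ratio scaling and the edgeR adjusted p was 8.38e-05. Sparc, a collagen-binding matrix protein and the most abundant member, rose from 53.5 and 52.3 to 126 and 105 units. After median-ratio scaling 12 members were called, by edgeR 11, and without knockdown replicate 3 the number was 3. Sparc was not called without knockdown replicate 3 or 4 (limma adjusted p = 1.0 and 0.189).

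Endothelial markers rose too. Of 17 tested members 6 rose over all genes and 16 adjusted over the list alone, all 17 lay above the median of all genes, and the median log2 fold change was 0.59 (camera adjusted p = 1.93e-16; adjusted p = 0.738 with an estimated correlation). Vwf, which encodes von Willebrand factor, rose from 2.91 and 3.70 to 15.1 and 8.90 units, and the endothelial transcription factor gene Sox18 from 3.49 and 2.96 to 13.3 and 8.65 units. Eng, the coreceptor endoglin and the most abundant member, rose from 28.6 and 25.0 to 69.6 and 45.5 units, and overlaps Fpgs. After scaling 4 members were called, by edgeR 4, and by limma with no filter on low values 1. Without that filter Vwf, Sox18 and Eng were not called (limma adjusted p = 0.0672, 0.0731 and 0.103). Limma called 13 without control replicate 1, 4 without knockdown replicate 4, and 0 without knockdown replicate 3.

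Among duct markers 7 of 15 tested members rose over all genes and 9 adjusted over the list alone, with a median log2 fold change of 0.43 (camera adjusted p = 4.74e-11; adjusted p = 0.738 with an estimated correlation). Spp1, osteopontin, rose from 252 and 251 to 720 and 373 units. Anxa3, an annexin, rose from 6.97 and 11.8 to 40.9 and 19.6 units, and Lgals3, which encodes galectin-3, from 6.97 and 6.17 to 28.2 and 18.3 units. After scaling 3 members were called and by edgeR 4. With no filter on low values limma called 1 member and after quantile normalization 2. Anxa3 was called in neither setting (limma adjusted p = 0.0911 and 0.0655), and Spp1 was not called with no filter (limma adjusted p = 0.126). Limma called 0 without knockdown replicate 3, and Spp1 was not called without knockdown replicate 4 (limma adjusted p = 0.0840).

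Acinar markers, which report digestive-enzyme cells, did not follow these lists. Of 25 tested members 0 were called by limma, 2 had an unadjusted p under 0.05, and edgeR and the fit adjusted over the list alone called 0. All 25 lay below the median of all genes, with a median of -0.41 (camera adjusted p = 7.64e-12; adjusted p = 0.915 with an estimated correlation). The most abundant member, Ctrb1, a chymotrypsinogen, stood at 1001 and 2057 units in the controls and 1767 and 828 in the knockdown libraries. Try5, a trypsinogen, stood at 168 and 476 against 275 and 150 units, and Pnliprp2, a lipase-related protein, at 20.1 and 45.5 against 30.0 and 14.8. In all 3 genes the groups overlapped. The direction of the list rested on single libraries. Without control replicate 2 the median was 0.23 (camera adjusted p = 2.90e-04; adjusted p = 0.948 with an estimated correlation) and 3 members rose, without knockdown replicate 4 it was 0.03 (camera adjusted p = 0.784), and without control replicate 1 it was -1.05 and 21 members fell.

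Macrophage and myeloid markers had a median of -0.01 and a mean of 0.12 (camera adjusted p = 0.639, upward), and the median turned to 0.02 after median-ratio scaling. Of 15 tested members 2 rose, over all genes and adjusted over the list alone, and 1 by edgeR. Lyz2, a lysozyme, rose from 1.60 and 0.370 to 6.78 and 5.60 units, and Cd14, a lipopolysaccharide coreceptor, from 2.62 and 5.67 to 12.8 and 8.90 units. Cd14 was not called after scaling (limma adjusted p = 0.114) or without control replicate 1 (0.0754), and neither gene was called without knockdown replicate 3 (limma adjusted p = 0.632 for Cd14 and 0.0952 for Lyz2). Cd74, the most abundant member, stood at 28.6 and 20.8 against 27.9 and 20.3 units.

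Red blood cell markers had a median of 0.52 (camera adjusted p = 0.0775) with 0 of 6 members called by limma over all genes or by edgeR, 2 adjusted over the list alone and 2 at an unadjusted p under 0.05. Hbb-bs and Hbb-b1 hold identical values in the table, 1.74 and 2.47 against 7.56 and 2.80 units, so that their reads are shared. They are the members behind each count of 2 for this list, so that these counts rest on the same reads. The list test took them as separate members. The list was called after scaling (camera adjusted p = 0.0331; adjusted p = 0.675 with an estimated correlation), with no filter on low values (camera adjusted p = 0.0219; adjusted p = 0.978 with an estimated correlation), without the trend (camera adjusted p = 0.00323; adjusted p = 0.966 with an estimated correlation), without control replicate 2 (camera adjusted p = 0.0268; adjusted p = 0.854 with an estimated correlation) and without knockdown replicate 4 (camera adjusted p = 7.77e-05; adjusted p = 0.992 with an estimated correlation), where 2 members rose. Schwann and neural markers had a median of -0.01, a mean of 0.03 and a downward test (camera adjusted p = 0.907), and the median turned to 0.03 after scaling, with 0 of 8 called by limma over all genes, adjusted over the list alone or by edgeR, and 1 at an unadjusted p under 0.05. Mbp, a myelin protein, stood at 70.6 and 68.3 against 82.7 and 70.5 units, Ngfr at 2.03 and 3.70 against 5.74 and 5.60, and Sox10 at 0.872 and 0.987 against 1.96 and 1.78. Lymphocyte and adipocyte markers had 3 tested members each and Y-linked genes 4, too few for the list test, and 0 of these were called by limma over all genes or adjusted over the list alone, at an unadjusted p under 0.05, or by edgeR.

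Beta cell identity and maturity genes lay below the median of all genes in the knockdown islets, where the stellate, endothelial and duct markers had medians of 1.13, 0.59 and 0.43. Of 27 tested members 25 lay below the median of all genes, with a median log2 fold change of -0.27 (camera adjusted p = 6.14e-07; adjusted p = 0.957 with an estimated correlation). By limma 0 were called over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and edgeR called 2 lower. The genes with the largest statistics were Trpm5, a calcium-activated cation channel, at 43.2 and 36.4 against 23.5 and 28.9 units (-0.75 ± 0.25 SE, limma adjusted p = 0.278), and Ffar1, a fatty acid receptor, at 34.6 and 26.4 against 22.6 and 22.1 units (-0.59 ± 0.25 SE, limma adjusted p = 0.618). Mafa, an insulin gene activator, stood at 183 and 125 against 113 and 122 units (-0.53 ± 0.23 SE, limma adjusted p = 0.669). Trpm5 and Mafa fell after median-ratio scaling (limma adjusted p = 0.0122 and 0.0208) and in the edgeR test (adjusted p = 0.00628 and 0.0452). Without control replicate 2 limma called 7 members lower, and without control replicate 1 it called 1 higher and 0 lower and the list was no longer called (camera adjusted p = 0.0853). With median-ratio scaling it called 10 lower without knockdown replicate 4 and 0 without any other library.

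The insulin genes, Slc2a2 and Pdx1 overlapped between the groups and were not called, except that Slc2a2 was called lower without control replicate 2 (log2 fold change -0.54, limma adjusted p = 0.00617). Ins2 stood at 58452 and 46108 units in the controls and 48195 and 51995 in the knockdown libraries, and Ins1 at 29026 and 23460 against 26212 and 27836. Of the reads counted in genes outside the 13 other rows above 25000 units, the insulin genes made up 13.1% and 13.1% in the controls. In the knockdown libraries they made up 11.8% and 12.6%. Slc2a2, the glucose transporter of beta cells, stood at 240 and 175 against 140 and 203 units, and Pdx1, a beta cell transcription factor, at 91.0 and 61.9 against 72.5 and 76.7. Pdx1 overlaps Plut, which holds up to 0.537 of its level.

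Insulin exocytosis and excitability genes had a median of -0.10 (camera adjusted p = 0.306), which turned to 0.02 after quantile normalization and was called after median-ratio scaling (camera adjusted p = 0.00551; adjusted p = 0.675 with an estimated correlation). It was called upward without control replicate 1 (camera adjusted p = 0.0214; adjusted p = 0.899 with an estimated correlation) with 3 members higher, and downward without control replicate 2 (camera adjusted p = 2.90e-04; adjusted p = 0.854 with an estimated correlation) with 1 lower. Of 30 members 0 were called by limma over all genes, adjusted over the list alone or by edgeR, and 1 had an unadjusted p under 0.05. The potassium channel genes Kcnj11 and Abcc8 stood at 105 and 84.5 against 80.3 and 85.2 units, and at 622 and 463 against 540 and 554. Chga, chromogranin A, stood at 5172 and 3874 against 3883 and 4332 units, Cacna1c, a calcium channel, at 160 and 105 against 174 and 181, and Exoc1, an exocyst subunit, at 17.7 and 11.8 against 21.6 and 20.9.

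Alpha cell markers had a median of -0.11 (camera adjusted p = 0.327), which was 0.05 without control replicate 2, with 0 of 12 called by limma over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or by edgeR. Gcg, glucagon, stood at 5422 and 6159 against 6652 and 6488 units, and Pou3f4 at 1.16 and 0.740 against 2.09 and 2.54. Delta and PP cell markers had a median of -0.22 (camera adjusted p = 0.294), with 0 of 11 called by limma over all genes, adjusted over the list alone or by edgeR, and 1 at an unadjusted p under 0.05. Without control replicate 1 limma called 2 of the delta and PP markers higher. Sst, somatostatin, stood at 911 and 760 against 794 and 788 units, Ppy, pancreatic polypeptide, at 1158 and 1036 against 1521 and 1185, and Hhex, a delta cell transcription factor, at 8.14 and 3.70 against 10.6 and 9.28.

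The list of genes normally kept silent in beta cells rose. Of 19 tested members 7 rose over all genes and 12 adjusted over the list alone, with a median log2 fold change of 0.55 (camera adjusted p = 1.93e-13; adjusted p = 0.738 with an estimated correlation). Tgm2, a transglutaminase, rose from 9.30 and 6.41 to 32.3 and 20.9 units, and Lcn2, a siderophore-binding lipocalin, from 18.6 and 14.1 to 53.3 and 32.2. Ldha, lactate dehydrogenase A and a member of the glycolysis list too, stood at 19.5 and 29.1 against 53.2 and 25.7 units. The medians of the stellate, endothelial and duct markers, at 1.13, 0.59 and 0.43, rose in the same libraries. After scaling 2 members were called, by edgeR 3, and by limma without knockdown replicate 3 the number was 0.

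**Figure D2:**
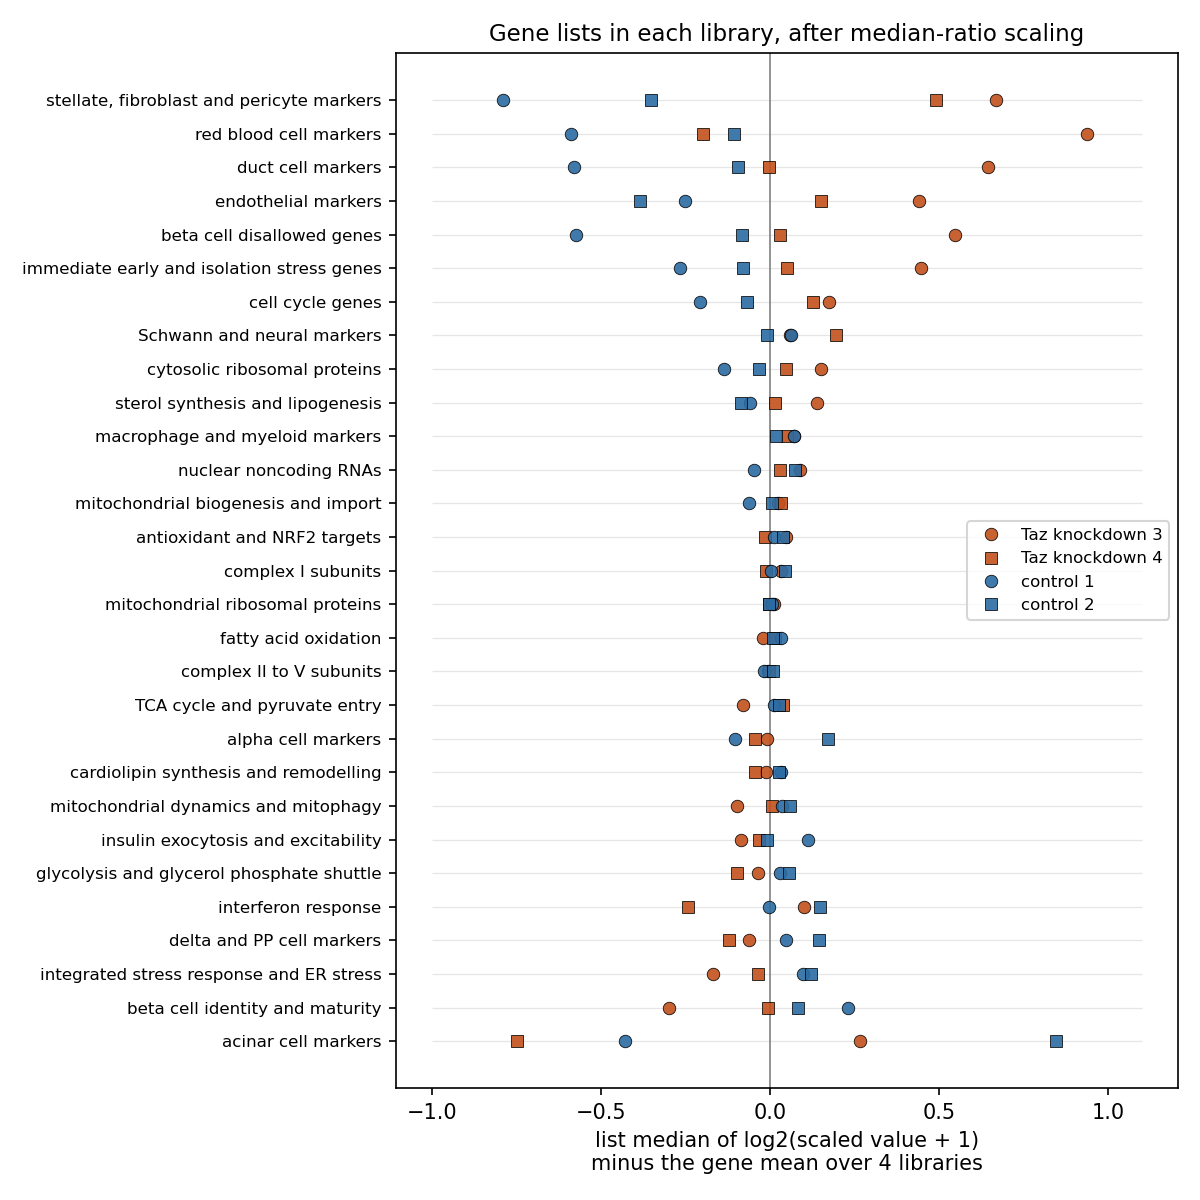
Median of each of the 29 tested gene lists in each library after median-ratio scaling, as log2 of the scaled value plus 1 minus the gene's mean over the 4 libraries. Points are single libraries, blue for control (circle, replicate 1; square, replicate 2) and orange for knockdown (circle, replicate 3; square, replicate 4). The stellate list lies at -0.79 and -0.35 in the controls and 0.67 and 0.49 in the knockdown, the beta cell identity list at 0.23 and 0.08 against -0.30 and -0.01, and the acinar list overlaps.

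Mitochondrial gene groups, the ones nearest to the function of Tafazzin, showed no call on the deposited values. The cardiolipin synthesis and remodelling list had a median of -0.03 over 23 members (camera adjusted p = 0.778). Cds2, a CDP-diacylglycerol synthase, stood at 141 and 102 against 135 and 131 units, and the prohibitins Phb and Phb2 at 4.36 and 5.92 against 10.2 and 6.61, and at 40.7 and 27.3 against 48.3 and 44.0. Complex I subunits had a median of -0.03 over 37 members (camera adjusted p = 0.778), and subunits of complexes II to V 0.04 over 40, with a mean of -0.01 and an upward test (camera adjusted p = 0.990). Ndufb2 stood at 12.9 and 8.76 against 16.7 and 18.4 units, Ndufa11 at 22.1 and 22.3 against 31.3 and 29.4, Atp5b at 300 and 264 against 320 and 332, Atp5o at 25.6 and 18.0 against 33.6 and 30.1, and Cox7c at 1.45 and 2.71 against 4.04 and 4.83. The tricarboxylic acid cycle list had a median of -0.04 over 34 members (camera adjusted p = 0.50), which was 0.01 without knockdown replicate 3, with Ogdh at 199 and 161 against 189 and 196 units and the pyruvate dehydrogenase kinase gene Pdk2 at 18.6 and 12.1 against 7.04 and 15.0, and Me3, a malic enzyme, at 3.05 and 1.48 against 4.70 and 3.18. Fatty acid oxidation had a median of -0.05 over 27 members (camera adjusted p = 0.778), which was 0.01 without knockdown replicate 3, with Hadh at 274 and 192 against 194 and 262 units, Hadhb at 7.26 and 8.88 against 13.2 and 13.5, and Pparg, a nuclear receptor, at 12.3 and 5.92 against 14.0 and 12.6.

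Mitochondrial dynamics and mitophagy had a median of -0.04 over 24 members (camera adjusted p = 0.514), with Sqstm1 at 472 and 380 against 452 and 477 units, Park2 at 36.6 and 29.6 against 49.0 and 45.8, and Chchd3 at 34.6 and 26.4 against 43.6 and 35.1. Mitochondrial biogenesis and import had a median of 0.04 over 25 (camera adjusted p = 0.558), with Hspa9 at 208 and 173 against 203 and 215 units, Tomm22 at 9.88 and 13.6 against 16.4 and 21.1, and Timm44 at 9.88 and 7.65 against 14.6 and 13.2. Mitochondrial ribosomal proteins had a median of 0.02 over 78, with a mean of -0.02 and a downward test (camera adjusted p = 0.946), and the median turned to -0.02 after quantile normalization. Mrpl36 stood at 12.5 and 12.1 against 18.8 and 21.0 units and Mrpl33 at 8.57 and 7.03 against 16.7 and 11.2. Mrps25, at 30.2 and 23.6 against 30.8 and 30.0 units, overlaps Nr2c2, whose level is higher. In these 8 lists limma called 0 members over all genes or adjusted over the list alone, edgeR called 0, and the members at an unadjusted p under 0.05 numbered 1, 1, 2, 0, 3, 1, 2 and 7 in the order given. Without control replicate 1 limma called 2, 1, 3, 1, 2, 1, 1 and 2 members higher, and without control replicate 2 it called 1 of biogenesis and import. In data simulated at the totals of these libraries, 14.9% of genes changed 1.5-fold were called, so that most changes of that size in single genes can be missed. The parts that depth and the number of libraries play in this were not tested.

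Glycolysis and the glycerol phosphate shuttle had a median of -0.06 over 26 members (camera adjusted p = 0.558), and 1 member rose, over all genes and adjusted over the list alone. This was Hk2, a hexokinase, from 1.45 and 0.740 to 5.74 and 4.07 units, which was not called after scaling (limma adjusted p = 0.0652), by edgeR (adjusted p = 0.0658), or without control replicate 2 or knockdown replicate 3 (limma adjusted p = 0.110 and 0.797). Aldoa, aldolase A, stood at 525 and 438 against 432 and 467 units. Sterol synthesis and lipogenesis had a median of 0.12 over 26 members (camera adjusted p = 0.0775), with 0 called over all genes, adjusted over the list alone or by edgeR, and 7 at an unadjusted p under 0.05. Hmgcs1, an early enzyme of sterol synthesis, stood at 44.5 and 35.4 against 74.9 and 53.7 units, Acly, ATP citrate lyase, at 2165 and 1617 against 1854 and 1909, and Scd1, a desaturase, at 5.52 and 9.50 against 13.6 and 11.1. The list was called with no filter on low values (camera adjusted p = 0.0198; adjusted p = 0.978 with an estimated correlation), at a mean of at least 5 units (camera adjusted p = 0.0445; adjusted p = 0.995 with an estimated correlation), scaled to the reads outside the 13 rows above 25000 units other than insulin (camera adjusted p = 0.0122; adjusted p = 0.642 with an estimated correlation), after quantile normalization (camera adjusted p = 0.00147; adjusted p = 0.575 with an estimated correlation) and without control replicate 1 (camera adjusted p = 0.00118; adjusted p = 0.899 with an estimated correlation), where 8 members rose.

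Antioxidant genes and NRF2 targets had a median of 0.01 over 23 members (camera adjusted p = 0.549), which turned to -0.00215 after median-ratio scaling, with 0 called by limma over all genes, adjusted over the list alone or by edgeR, and 4 at an unadjusted p under 0.05. Slc7a11, a cystine transporter, stood at 16.3 and 13.6 against 32.1 and 19.3 units, and Txnrd1, thioredoxin reductase, at 200 and 151 against 221 and 201. Without control replicate 1 limma called 5 of these antioxidant genes higher, and without control replicate 2 it called 1. Nqo1, at 4.94 and 3.33 against 8.87 and 8.14 units, overlaps a microRNA row with a far higher level. The interferon response had a median of -0.07 over 24 members (camera adjusted p = 0.294), with 0 called over all genes, adjusted over the list alone or by edgeR, and 1 at an unadjusted p under 0.05. Irf7 stood at 38.6 and 50.3 against 48.0 and 22.1 units and Oasl1 at 5.81 and 1.73 against 10.2 and 3.05. The interferon list was called downward without knockdown replicate 3 (camera adjusted p = 2.07e-05; adjusted p = 0.951 with an estimated correlation) and without control replicate 1 (camera adjusted p = 0.0202; adjusted p = 0.902 with an estimated correlation), and its median was 0.11 without knockdown replicate 4, where 2 members rose.

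Immediate early and isolation stress genes rose. Of 25 tested members 6 rose over all genes and 11 adjusted over the list alone, with a median log2 fold change of 0.43 (camera adjusted p = 9.26e-07; adjusted p = 0.738 with an estimated correlation). The cytokine gene Il6 rose from 2.03 and 2.96 to 14.6 and 7.63 units and the transcription factor gene Egr1 from 14.7 and 10.9 to 29.7 and 27.0. Jund, the most abundant member, stood at 143 and 116 against 157 and 150 units. After scaling 3 members were called and by edgeR 4. Limma called 10 without control replicate 1, 3 without knockdown replicate 4 and 0 without knockdown replicate 3, and Egr1 was not called without knockdown replicate 4 (limma adjusted p = 0.0670). Stellate markers, with a median of 1.13, rose in the same libraries.

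The list of the integrated stress response and endoplasmic reticulum stress lay below the median of all genes, with 24 of 27 members below it and a median of -0.23 (camera adjusted p = 0.0175; adjusted p = 0.957 with an estimated correlation). In the same libraries the medians of beta cell identity genes, acinar markers and stellate markers were -0.27, -0.41 and 1.13. The only called member of the stress list, over all genes and adjusted over the list alone, went the other way. Atf3, a stress-induced transcription factor, rose from 1.16 and 2.71 to 6.91 and 4.07 units and was not called by edgeR (adjusted p = 0.337), after scaling (limma adjusted p = 0.281), or without control replicate 1 or knockdown replicate 3 (limma adjusted p = 0.196 and 1.0). Hspa5, the chaperone BiP, stood at 889 and 772 against 755 and 854 units, and Gdf15 at 5.81 and 4.69 against 9.39 and 7.25. The list was not called without knockdown replicate 3 (camera adjusted p = 0.230) or without control replicate 1 (camera adjusted p = 0.0897).

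Cell cycle genes had a median of 0.26 over 19 members (camera adjusted p = 0.0358; adjusted p = 0.915 with an estimated correlation). Over all genes 1 member rose, and 5 did adjusted over the list alone. The replication helicase gene Mcm3 rose from 1.74 and 1.73 to 7.30 and 3.81 units, Mcm6 stood at 8.14 and 7.89 against 17.0 and 13.5, and Ccnd2, cyclin D2, at 640 and 445 against 513 and 626. The list was not called without control replicate 1, control replicate 2 or knockdown replicate 4 (camera adjusted p = 0.386, 0.149 and 0.0696). The medians of the stellate, endothelial and duct markers, at 1.13, 0.59 and 0.43, rose in the same libraries. The cell cycle list was also not called with no filter on low values, at a mean of at least 5 units, or scaled to the reads outside the 13 rows above 25000 units other than insulin (camera adjusted p = 0.0907, 0.178 and 0.0551). Mcm3 was not called after scaling (limma adjusted p = 0.198), by edgeR (adjusted p = 0.187), or without control replicate 2 or knockdown replicate 3 (limma adjusted p = 0.110 and 1.0), and without control replicate 1 limma called 5 members.

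Cytosolic ribosomal proteins had a median of 0.18 over 75 members, 62 of them above the median of all genes (camera adjusted p = 0.00353; adjusted p = 0.957 with an estimated correlation), and were not called without knockdown replicate 4 (camera adjusted p = 0.0790). The medians of the stellate, endothelial and duct markers, at 1.13, 0.59 and 0.43, rose in the same libraries, and a change in cell mix was not separated from this shift. Rpl13 alone rose, from 6.39 and 3.33 to 8.87 and 10.9 units, when tested over all genes, and limma called 0 adjusted over the list alone and 0 after scaling, edgeR 0, with 11 members at an unadjusted p under 0.05. Rpl4, the most abundant, stood at 300 and 245 against 323 and 326 units, and Rpl12 at 1.16 and 1.73 against 4.96 and 3.69. Limma called 20 members higher without control replicate 1, 3 without control replicate 2 and 0 without knockdown replicate 3 or 4. Nuclear noncoding RNAs had a median of 0.08 over 11 members, with a mean of -0.01 and an upward test (camera adjusted p = 0.778), and 0 were called by limma over all genes, adjusted over the list alone or by edgeR, and 2 at an unadjusted p under 0.05. Neat1 stood at 81.9 and 115 against 158 and 149 units and Malat1 at 1291 and 1713 against 2131 and 1861. The list was called without control replicate 2 (camera adjusted p = 0.0416; adjusted p = 0.854 with an estimated correlation), where 3 members rose, and 2 rose without control replicate 1.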

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

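Tests chosen only after the result was seen were DESeq2 and the fit of genes overlapping no other row. So were the scaling to reads outside the 13 rows above 25000 units other than insulin, and median-ratio scaling with a library left out. The plan had named edgeR as the main test if the file held counts. Here edgeR was run on recovered reads beside limma, which was kept as the main test. The cause was not tested for the changes below, except that settings with fewer libraries have fewer samples.

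Against 343 changed genes (337 higher, 6 lower), 80 changed (80 higher, 0 lower, with 1513 at an unadjusted p under 0.05 by limma; edgeR called 20 lower) with no filter on low values, 173 (151 and 22) after median-ratio scaling, 93 (86 higher) after quantile normalization, 544 (528 and 16) without the trend, 191 (171 and 20) by edgeR and 68 (59 higher) by DESeq2. Lower genes numbered 3 in the robust fit, 10 at a 10% threshold and 16 when scaled to reads outside those 13 rows. With median-ratio scaling limma called 0 genes (0 higher, 0 lower) without control replicate 1 and 0 (0 and 0) without control replicate 2, at 731 and 1256 genes with an unadjusted p under 0.05, 93 (45 and 48) without knockdown replicate 3, and 67 lower without knockdown replicate 4. Leaving out each library on the deposited values gave 30 to 1301 changed genes, 26 to 1264 higher and 3 to 59 lower. Of 29 lists, 10 were called by camera, 0 with an estimated correlation and 0 by fry. The Taz log2 fold change lay between -0.50 and -0.79 in every alternative run on it and passed the threshold in none.

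Over the 16 settings compared gene by gene, values for named genes kept direction and side of the threshold in 1403 cases, lost the call in 81, gained it in 46 and reversed in 32; for list medians, over 15 settings, these numbers were 377, 10, 16 and 27. DESeq2, the 10% threshold and median-ratio scaling with a library left out are not counted there, and in the fits of the last kind that called 0 genes every named call was lost. The reversed macrophage medians were 0.0181 and 0.00268 with pseudocounts of 0.1 and 0.5, 0.00509 with no filter, 0.0194 after median-ratio scaling, 0.0782 among genes overlapping no other row and 0.00271 when scaled to reads outside the 13 rows. The reversed antioxidant medians were -0.00136 with a pseudocount of 0.1, -0.00215 after median-ratio scaling and -0.0229 among genes overlapping no other row. Schwann medians were 0.0279, 0.0104 and 0.00936 after median-ratio scaling, among genes overlapping no other row and scaled to reads outside the 13 rows. After quantile normalization the exocytosis median was 0.0222, that of mitochondrial ribosomal proteins -0.0193, and the log2 fold changes that reversed were Gcg -0.0886, Cds2 0.0682, Ccnd2 0.0819, Chga 0.0184, Hspa9 0.0709, Sqstm1 0.165, Mbp 0.0221, Acly 0.0709, Ogdh 0.0381, Abcc8 0.0741 and Ins1 0.0184. By edgeR Gcg was at -0.0166.

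Leaving out each library reversed list medians over these ranges: alpha -0.215 to 0.0495, acinar -1.05 to 0.228, macrophage -0.0606 to 0.0150, Schwann -0.168 to 0.159, tricarboxylic acid cycle -0.111 to 0.00931, fatty acid oxidation -0.0506 to 0.00692, mitochondrial ribosomal proteins -0.00948 to 0.0321, antioxidant -0.00487 to 0.101 and interferon -0.252 to 0.110. The genes that reversed ranged as follows: Ctrb1 -1.07 to 0.242, Pnliprp2 -1.37 to 0.0383, Try5 -1.53 to 0.239, Gcg -0.208 to 0.245, Cds2 -0.116 to 0.0788, Ccnd2 -0.240 to 0.0723, Ppy -0.0443 to 0.291, Hadh -0.425 to 0.0349, Ldha -0.0531 to 0.944, Oasl1 -0.247 to 1.19, Cd74 -0.410 to 0.00174, Hspa9 -0.0821 to 0.0228, Sqstm1 -0.0891 to 0.0121, Mrps25 -0.0237 to 0.0535, Malat1 -0.0834 to 0.593 and Mbp -0.143 to 0.0791.

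Small changes can be missed: in data simulated at the totals of these libraries, with 2 libraries per group, 14.9% of genes changed 1.5-fold were called. Between 4320910 and 4962798 reads per library were counted in genes outside the 13 rows, and the part that depth or the number of libraries plays in this was not tested.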

Other observations

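The lists of YAP targets and of the interleukin 6 family, the lower genes named here, and the tests of explanations were chosen only after the values were seen.

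Wwtr1 and YAP are coactivators of the Hippo pathway, and of 20 tested genes known as their targets 6 rose over all genes by limma, 4 after scaling and 5 by edgeR. This list and that of the interleukin 6 family hold genes whose increase had been seen before (Myof, and Il11 and Il6), so that their counts are descriptions and no test of either list is given. Ctgf and Cyr61, which encode secreted matricellular proteins, rose from 8.43 and 8.39 to 35.5 and 21.1 units and from 5.81 and 5.67 to 30.8 and 17.8 units, and Ankrd1, an ankyrin repeat protein, rose from 1.16 and 1.23 to 13.6 and 5.60 units. These genes are also expressed by stromal and duct cells, whose markers rose in the same libraries (medians 1.13 and 0.43). Ligands and receptors of the interleukin 6 family had 6 of 12 members higher over all genes by limma, 3 after scaling and 4 by edgeR. Lif, a cytokine, rose from 4.65 and 3.70 to 21.4 and 16.3 units and the receptor gene Osmr from 2.33 and 2.22 to 10.4 and 5.60 units, while the shared receptor gene Il6st stood at 103 and 80.4 against 130 and 101 units. Osmr was called by edgeR (adjusted p = 0.0440) but not after scaling (limma adjusted p = 0.0539). Of this list 1 gene, Il6, also belongs to the immediate early list.

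Besides Scarna6 and Derl3, the lower calls were Reg3g, Reg3a, Reg2 and Snord17. The Reg genes encode secreted C-type lectins of the exocrine pancreas. Reg2 stood at 51.4 and 142 units in the controls and 94.4 and 23.5 in the knockdown libraries, Reg3g at 9.44 and 25.3 against 13.2 and 3.05, and Reg3a at 5.23 and 18.5 against 9.39 and 1.27, so that their groups overlapped, and none of the 3 was called by limma after scaling or by edgeR. Snord17, a small nucleolar RNA inside Snx5, fell from 16.4 and 11.5 to 7.83 and 4.83 units (limma adjusted p = 0.00769). The row of Snx5 holds 6.67 times its level. Scarna6 and Snord17 were the only lower genes called by limma on the deposited values, by limma after scaling and by edgeR. Both are small RNAs inside a gene with a higher level, from whose reads theirs cannot be told apart.

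The stellate and endothelial markers were higher in the knockdown, with all 38 tested members above the median of all genes. After median-ratio scaling the median of both lists was 0.83, with an SD between libraries of 0.16. This scaling brings the median of all genes close to 0, and both lists were known to lie above that median. The outcome was thus largely fixed by the measure, and no conclusion about scaling is drawn from it. The stellate median rose above the macrophage median by 1.13 (SD 0.26), so that these 2 lists did not rise alike. A smaller endocrine share that raised all other cell types alike would raise both. Both medians were known before this comparison was set, so it is no independent test of that share. Only 8 of the 15 macrophage markers had a mean of at least 5 units, and changes at low values are understated. More stromal and vessel cells in these preparations and a higher level per cell cannot be told apart in bulk RNA, since either may put 38 of 38 members above the median. An effect of the knockdown on either stays open and untested.

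Beta cell identity genes lay below the median of all genes in 25 of 27 members. With a pseudocount, a factor applied to a whole library moves genes at low values less than abundant ones. Scaling can therefore shift a list against the median of all genes. Median-ratio scaling carried 3 of 29 list medians across it, such as the macrophage median from -0.01 to 0.02. The median of the beta list was -0.27 on the deposited values and -0.29 after median-ratio scaling, so that this scaling did not remove its shift. A test of scaling made here was dropped because the measure largely fixed its outcome. The libraries were uneven, at 0.23 and 0.08 in the controls and -0.30 and -0.01 in the knockdown after that scaling. Dilution by other cell types cannot be told apart from a change in beta cells alone, since the beta list lay below the alpha list by a difference of -0.25 with an SD of 0.27, which 2 libraries per group do not resolve. A lower level per beta cell in the knockdown may account for the shift as well and was not tested.

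The median log2 fold change of all genes was 0.17. Without control replicate 2 the median was 0.0315. In that library the genes outside the 13 rows above 25000 units other than insulin held 5.33% of the library total, against 6.31% to 6.68% in the other libraries. Its median-ratio size factor was also the lowest, at 0.851 against 1.04 to 1.08. The fall of the median thus follows from its low values and cannot tell a low gene share from another source of the shift. The median was 0.301 without control replicate 1, and 0.158 and 0.183 without knockdown replicates 3 and 4. Scaled to the reads outside those rows the median was 0.0902, which lies between the bounds set for the test, so that unequal shares of these rows cannot be told apart from a change spread over many genes. A biological shift of all genes was not tested.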
